A study of Canis lupus familiaris with 4 samples.

How the data were processed

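Total RNA of 4 canine adipose MSC cultures, 1 per dog, was sequenced. Per the labels' protocols, the cells grew in DMEM with 10% fetal bovine serum, were seeded in multiwell plates and harvested after 48 h, and libraries were made from 10 ng of RNA with a stranded total RNA kit that depletes ribosomal RNA. Per the submitters' processing notes, FastQC 0.12.1, Trimmomatic 0.39, STAR 2.7.11a and DESeq2 were used with the canine genome build CanFam3.1. The read counter, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited values are on a log2 scale and were transformed by the authors with the variance-stabilizing transformation of DESeq2, per the file headers, and they hold 30951 Ensembl genes, 17896 of them with a symbol. The columns of the table carry the Italian word for dog with the dog number and were matched to the samples by that number. No column of per-sample values was left unused.

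The transformation has a closed inverse once the value of 0 reads is known, which was the lowest value of the table. The inverse gave values that are whole multiples of 1 step per library: 100% of the non-lowest values in each library came out whole within 0.01 reads, with a largest deviation of 0.00203. Dividing by the step gave the reads per gene, totals of 22411268, 16246965, 15203607 and 7474011 for dogs 1 to 4 and size factors of 1.39, 1.08, 1.05 and 0.461. The reads served for depth, limits and read shares, and all tests ran on the deposited log2 values. A value near the floor understates a fold, since the transformation flattens there, and 1 read in dog 4 raises a value more than 1 read in dog 1. Levels were not corrected for gene length, so they compare a gene with itself between dogs more safely than long with short genes. The 10 most abundant genes took 20.6% to 22.3% of reads.

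A gene's level was its value minus the library's median over detected genes (reads in at least 2 of 4 libraries). Levels were tested in limma 3.58.1 (R 4.3.3) with an intercept-only fit, a trended prior and a distance of 1 log2 unit, and adjusted by Benjamini-Hochberg with a threshold of 0.05. Variability between dogs was tested as the ratio of a gene's variance to limma's trended prior variance by an F test. Gene lists numbered 33, fixed before the data were examined, and hold 868 entries, of which 725 are in the table. A gene may stand in several lists. For symbols with several rows the row with the highest mean was used. Members were counted by their call, also adjusted over the list alone: the counts were the same except for antimicrobial chemokines (7 in place of 6 below) and neural and Schwann genes (4 in place of 3 below). List medians were compared within each dog by an exact two-sided sign-flip permutation test over 16 sign patterns. List levels were set against 10000 random lists of named genes, and list spreads against 10000 random lists matched on level in 20 bins (numpy 2.4.6, pandas 2.3.3). The middle 95% of random lists ends at percentile 97.5. A library stood apart for a gene when its gap to the nearest other, divided by the range, exceeded Dixon's 0.829.

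The level test was tested on simulated data over 18598 genes. It recovered 100% of 50 genes set 2.5 below the median gene, 98% at 2 below, 100% at 2 above and 100% at 3 above, and called 2% of 200 genes placed within the distance. The variability test recovered 49% of 100 genes with an SD of 1.5 and 80% with an SD of 2.5, and 0.769% of its calls were unchanged genes. The unchanged genes were all simulated with the same SD between dogs, plus counting noise, unlike the real genes. Recovery in the real data may therefore be lower: the gene SORCS1, with an SD of 2.82, did not pass there. Replicates are separate dogs per the library names, so the p-values of the level test use the spread between dogs, moderated over genes, as error. With 1 culture and 1 library per dog, that spread includes differences between cultures and libraries. Alternatives covered the reference gene set, the distance, quantile normalization, a log2 scale with a pseudocount of 1, low-value filters, the prior, the list summary, leaving out each dog and, chosen after seeing the data, thinning all libraries to the shallowest.

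Named genes followed a rule fixed before the data were examined: up to 10 highest and 5 lowest members of the antimicrobial peptide and MSC marker lists, up to 4 highest and 2 lowest of each other list and any member past the variability test, the 20 most abundant genes, the 20 most variable past the test (none passed) and, per library, the 5 genes standing farthest apart. The 10 genes with the largest SD and these genes: AIF1, C1S, C2, C3, CAMP, CCL22, CD34, CDKN1A, CSF3, CXCL12, CXCL13, CXCL14, DEFB1, DEFB129, DGUOK, DLA88, ELN, ENG, FBN2, FCER1G, HAMP, HGF, IDO1, IGF1, IL10, IL11, IL18, IL1B, LYZ, MCAM, MPO, MYH11, PGLYRP1, POSTN, PTGES, PTGS2, PTX3, S100A12, SAA1, SFTPD, SPI1, THY1, TLR3, TLR4, TNF and TNFAIP6 were chosen after their values were seen. Some genes that the rule or the lists take are counted in their lists and not reported here by name. Symbols of the table matched the RefSeq gene table of assembly UU_Cfam_GSD_1.0 in 97.0% of cases. That table, of another build, was used only for which genes neighbour each other, and no coordinates were taken from it. Reads of genes with near-identical copies, such as ACTG1 and ACTB, EEF1A1, the DLA genes and ribosomal proteins, are uncertain, as are the overlapping MT-ATP8 and MT-ATP6.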

Results

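Total RNA was sequenced from adipose tissue-derived mesenchymal stromal cells (MSCs) of 4 dogs, with 1 library per dog. MSCs are plastic-adherent, matrix-producing progenitor cells, and the series title places them in a study of the antimicrobial activity of their lyosecretome, the freeze-dried mixture of proteins and vesicles that such cells release. Each library came from a separate primary cell line, cultured untreated for 48 h. The labels give 1 group only, so no contrast between conditions was made. The level of each gene was set against the median detected gene of its own library, and the spread between the 4 dogs was the error. Reads assigned to genes numbered 22411268 for dog 1, 16246965 for dog 2, 15203607 for dog 3 and 7474011 for dog 4, and the genes with at least 1 read numbered 17023, 16921, 16090 and 16538. A gene was called detected when at least 2 of the 4 libraries held reads of it, which held for 17200 of 30951 genes.

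Collagen and matrix transcripts were the most abundant among named genes; in dog 4 a gene without a symbol, at 6.54% of reads, lay above COL3A1. The most abundant named genes were COL3A1, COL1A1 and COL1A2, which encode the chains of the fibrillar collagens, at levels of 12.13 ± 0.16, 11.80 ± 0.39 and 11.37 ± 0.27 above the median detected gene (log2, mean ± SD, n = 4 dogs, as for all levels given with ± here). The mitochondrial oxidase gene MT-CO1 followed at 10.55 ± 0.32. COL5A1, the actin cross-linker FLNA, fibronectin (FN1), COL5A2, THBS2, the endocytic receptor LRP1, ACTG1, VIM, ACTB and HSPG2 were also among the 20 highest. Of the 39 measured members of the collagen and matrix list, 36 were above the median detected gene and none below, and the list held 19.7% ± 1.28 of the reads. Across the transcriptome, 5723 of the 17200 tested genes were more than 1 log2 unit above the median detected gene, 6163 were more than 1 below and 5314 were neither (limma, distance 1, Benjamini-Hochberg). These counts hang on the reference: 3729 were above and 7479 below when the median was taken over the 13834 genes with reads in all 4 dogs, and 11406 above and 0 below when it was taken over all genes in the table.

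At the RNA level, most genes of the expected MSC surface marker list were above the median detected gene, though not NT5E. Few marker genes of blood or endothelial cells were. Surface proteins were not measured. Of 27 expected MSC markers, 18 were above the median detected gene, 2 below and 7 neither. The integrin chains ITGA5, ITGAV and ITGB1 led with levels of 7.91 ± 0.53, 7.64 ± 0.14 and 6.99 ± 0.52. The platelet-derived growth factor receptor PDGFRB stood at 5.53 ± 0.32, the hyaluronan receptor CD44 at 5.46 ± 0.31, PDGFRA at 4.76 ± 0.64, THY1 at 4.65 ± 0.63 and ENG at 2.41 ± 0.19. The ectonucleotidase gene NT5E, which encodes CD73, was below at -2.17 ± 0.50, with 47, 20, 21 and 3 reads in dogs 1 to 4, and the nerve growth factor receptor NGFR was below at -2.98 ± 0.66. Without dog 4, 4 of these markers were below. VCAM1, L1CAM and MCAM did not pass the test, at -1.52 ± 0.84, -1.33 ± 0.26 and -0.35 ± 0.16, but VCAM1 was below without dog 4 (-2.16) and L1CAM without dog 1 (-1.63), 2 (-1.69) or 4 (-1.53).

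Of 18 markers expected absent from MSCs, 13 were not detected, 3 were below the median detected gene, 1 was neither and 1 was above. CD79B, MS4A1, PECAM1, CD86 and HLA-DQB1 had 0 reads in all 4 dogs, PTPRC had 5 reads in dog 3 alone and CD34 had 4 reads in dog 3 alone. The costimulatory receptor CD40 was neither, at -0.15 ± 0.71. The exception was CD79A, a chain of the B-cell receptor, at 5.31 ± 0.17, with 10221, 6399, 6692 and 2627 reads. In the dog RefSeq annotation CD79A lies beside the ribosomal protein gene RPS19, which was not analysed here under its own symbol. The median of the expected markers exceeded that of the expected-absent markers by 7.60 ± 0.45, and it exceeded those of the endothelial, epithelial and mesothelial, and adipocyte lists by 6.86 ± 0.35, 7.02 ± 0.80 and 5.08 ± 0.22, each in 4 of 4 dogs. The exact two-sided sign-flip test gave each of these the smallest p that 4 dogs allow, 2 of 16 sign patterns (0.15 after Benjamini-Hochberg adjustment over 12 differences), so no difference could pass 0.05. The median of the expected-absent list lies at the value of 0 reads, so its difference is bounded by that floor, and the myeloid and lymphoid medians, at the same floor, gave the same 7.60 ± 0.45.

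**Figure D1:**
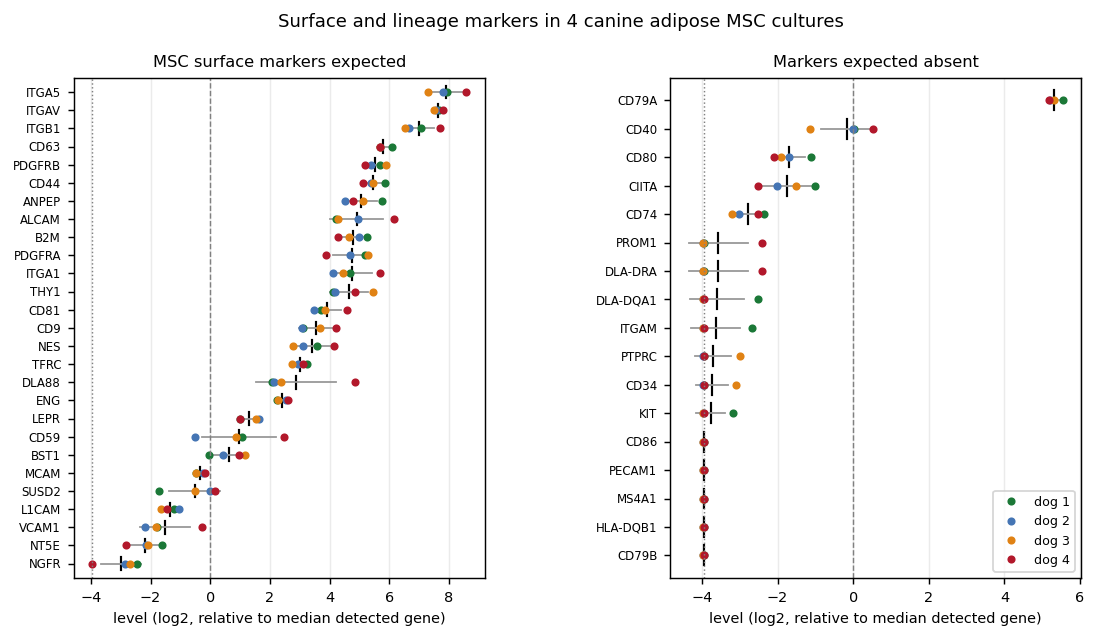
Levels of expected MSC markers (left) and of markers expected absent that are reported here (right), log2 relative to the median detected gene of each library (x axis, dashed line at 0, dotted line at the value of 0 reads). Points are dogs, black ticks means and grey bars ± SD over 4 dogs; CD79A, at 5.31, has the only mean above 0 among the markers on the right.

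The measured genes of classical antimicrobial peptides and proteins were mostly silent or at a few reads in the untreated cells. Of the 54 entries of the list, 32 were measured under their symbol, and the rest could not be assessed. Of the 32 measured genes, 3 were above the median detected gene, 9 below, 3 neither and 17 not detected. Of the undetected genes, 13 had 0 reads in every dog, including the cathelicidin CAMP, the beta-defensin DEFB1, lysozyme (LYZ), the leukocyte protease inhibitor SLPI and the bactericidal protein BPI. Over the 61335851 reads of all 4 libraries, 0 reads allow a level of up to 0.0489 CPM (counts per 1e6 assigned reads), and in the single libraries of dogs 1 to 4 up to 0.134, 0.185, 0.197 and 0.401. These limits, set at 3 reads, cover counting error only. The median of the list lay between the 0 and 0.02 percentiles of 10000 random lists of the same size, drawn from all named genes, in the 4 dogs. With 17 of the 32 genes not detected, that median lies at the value of 0 reads.

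The 3 antimicrobial genes above the median were S100A8, GRN and ADM. S100A8 (ENSCAFG00000017557) encodes a subunit of calprotectin, which withholds zinc and manganese from microbes, and it stood at 4.76 ± 0.37 with 4414 ± 1083 normalized reads (limma, Benjamini-Hochberg adjusted p = 1.09e-08, n = 4, above in 4 of 4 dogs). Its partner S100A9 and its neighbour S100A6 were not analysed here under those symbols, and the neighbouring S100A12 was below at -3.54 ± 0.49. Progranulin (GRN) stood at 4.45 ± 0.10 with 3487 ± 275 normalized reads, the steadiest of the 3 between dogs. Adrenomedullin (ADM), a vasoactive peptide with antimicrobial activity, stood at 2.97 ± 0.79. The siderophore-binding lipocalin LCN2 (0.84 ± 1.12), the beta-defensin CBD103 (-1.35 ± 0.60) and lactoferrin (LTF, -1.64 ± 1.10) were neither above nor below, with 585, 523, 327 and 33 reads of LCN2 in dogs 1 to 4 and 56, 103, 35 and 12 reads of CBD103. CBD103 belongs to a family of near-identical copies, so its reads are uncertain. CBD103 was below without dog 2 (-1.89), and LTF without dog 1 (-2.21) or 4 (-2.19). LEAP2, RNASE4, PI3, ELANE, MPO, PGLYRP1, HAMP, S100A12 and DEFB129 were below. When only genes with reads in all 4 dogs were tested, 2 were below, and when every gene of the table was tested, undetected ones included, 25 were.

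**Figure D2:**
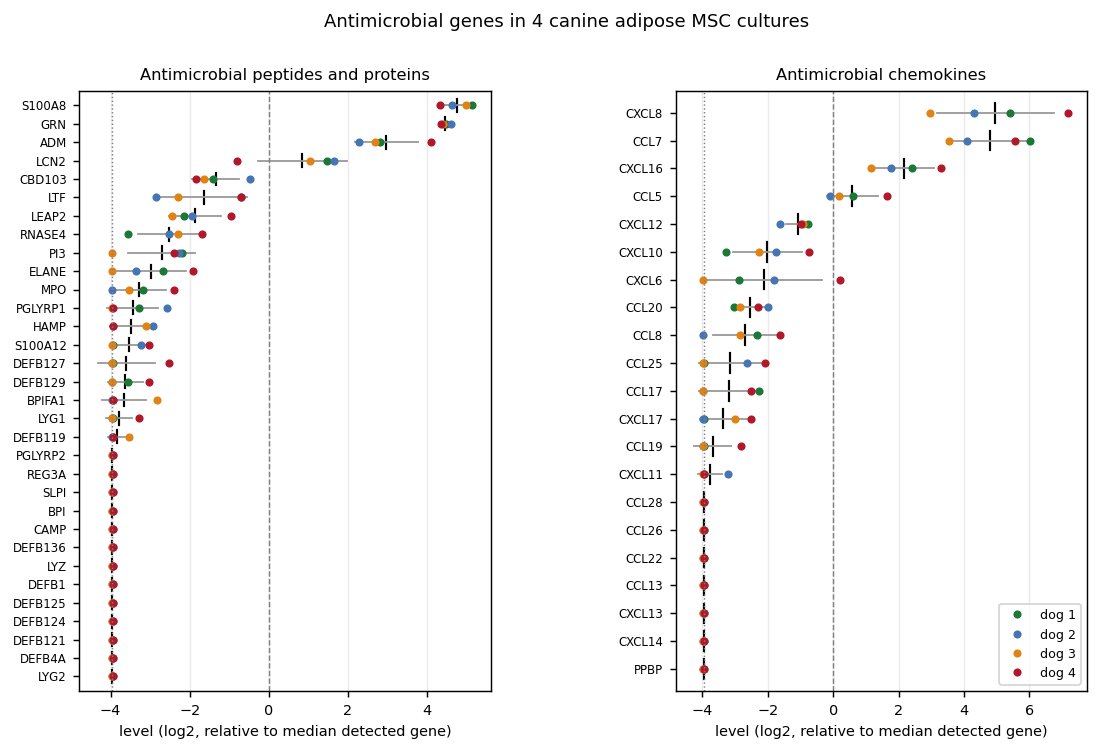
Levels of antimicrobial peptides and proteins (left) and of antimicrobial chemokines (right), log2 relative to the median detected gene of each library (x axis, dashed line at 0, dotted line at the value of 0 reads). Points are dogs, black ticks means and grey bars ± SD over 4 dogs; S100A8, GRN and ADM lie at 4.76, 4.45 and 2.97, and CXCL8 and CCL7 at 4.96 and 4.80 with a wide spread.

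Chemokines with antimicrobial activity split into a few abundant genes and many near the floor. Of 21 measured, 3 were above the median detected gene, 6 below, 3 neither and 9 not detected. The neutrophil attractant CXCL8 reached 4.96 ± 1.79, with 6687, 3160, 1227 and 23066 normalized reads in dogs 1 to 4. The monocyte attractant CCL7 stood at 4.80 ± 1.17 and the membrane-bound chemokine CXCL16 at 2.16 ± 0.91. CCL7 lies beside CCL2, which was not analysed here under its own symbol. CCL5 (0.59 ± 0.78) and the stem cell attractant CXCL12 (-1.08 ± 0.37) were neither. CXCL13, CXCL14, CCL22, CCL26 and CCL28 had 0 reads in all dogs.

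Soluble innate factors and complement genes were mixed. Of 29 measured members, 8 were above the median detected gene, 8 below, 4 neither and 9 not detected. THBS1 (8.88 ± 0.93), CLU (4.11 ± 0.36), C1R (3.87 ± 0.14) and PROS1 (3.80 ± 0.82) were the highest. The C1 protease C1S, the acute-phase protein SAA1, C2 and the long pentraxin PTX3 (3.19 ± 0.71) were the other 4 above. The central complement gene C3 was below at -2.36 ± 0.48, and C5 and the lectin-type gene SFTPD had 0 reads. Among 23 pattern recognition genes, the intracellular sensor NOD1 (2.66 ± 0.44) and the adaptors MYD88 (1.82 ± 0.33) and TICAM1 (1.44 ± 0.29) were above, 10 were below and 6 neither. TICAM1 lost its call without dog 1 (1.18), 2 (1.19) or 4 (1.09). TLR4, the receptor of bacterial lipopolysaccharide, was below at -2.18 ± 0.26, while TLR5 (1.23 ± 0.87) and TLR3 (0.11 ± 0.53) did not pass the test. In the metal-withholding list 7 of 20 were above, 4 below and 7 neither. The ferritin chains FTL (5.65 ± 0.20) and FTH1 (4.46 ± 0.36), the zinc and iron importer SLC39A14 (4.71 ± 0.47) and S100A8 led it.

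The median of the antimicrobial peptide list was set against those of other secreted-factor groups within each dog. It lay below the soluble innate and complement list by 1.52 ± 0.39 log2 units (list difference -1.52), below the immunomodulatory list (-2.85 ± 1.28), below secreted growth factors (-3.63 ± 0.54) and below genes of extracellular vesicle biogenesis (-7.01 ± 0.16), each in 4 of 4 dogs. The exact sign-flip test again gave each the smallest p possible (0.15 after Benjamini-Hochberg adjustment). Its difference from the antimicrobial chemokines was 0 in dogs 1 to 3 and -1.42 in dog 4 (mean -0.36 ± 0.71, exact sign-flip p = 1). The median of the antimicrobial peptide list lies at the value of 0 reads in all dogs, so these distances are bounded by that floor. Levels were not corrected for gene length, so these differences between lists may also carry differences in length. The median of the chemokines lies there too in dogs 1 to 3, so the 0 in these dogs gives no comparison.

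Immunomodulatory genes of stromal cells were partly abundant. Of 30 measured, 9 were above the median detected gene, 7 below, 9 neither and 5 not detected. The galectins LGALS1 (5.18 ± 0.24) and LGALS3 (5.00 ± 0.76), the macrophage growth factor CSF1 (3.60 ± 0.61) and TGFB2 (3.58 ± 0.65) led, and prostaglandin E synthase PTGES (3.42 ± 1.05) and the hyaluronan-binding TNFAIP6 (2.25 ± 0.68) were above as well. The cyclooxygenase gene PTGS2 had a level of 2.01 ± 1.93 and did not pass the test. Indoleamine dioxygenase (IDO1) had 6 reads in dog 1 and 0 in the others, and IL10 had 2 reads in dog 1 alone. Of 17 pro-inflammatory cytokines, the death ligand TNFSF10 (3.20 ± 0.32) was above, 7 were below, 2 neither and 7 not detected. TNF, IL18 and IFNG had 0 reads in every dog, and IL1B was below at -2.25 ± 0.29. Interferon response genes divided evenly, with 7 of 28 above, 7 below and 12 neither, and SAMD9L (3.22 ± 0.25) and STAT2 (2.62 ± 0.27) among those above. The NF-kB and stress list had 21 of 28 members above and none below (1 below without dog 1 or 3 and 2 without dog 4), led by the endoplasmic reticulum chaperone HSPA5 (6.22 ± 0.24), ATF4 (5.60 ± 0.09), IER3 (5.16 ± 0.37) and ASNS (5.12 ± 0.20).

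Genes of growth factors were spread over all levels, and genes of vesicle biogenesis and matrix proteases lay mostly above the median. Among 60 secreted growth factors, 19 were above the median detected gene, 14 below, 19 neither and 8 not detected. The Wnt modulator SFRP2 (7.27 ± 0.31), VEGFA (7.03 ± 0.48), the procollagen protease BMP1 (5.65 ± 0.43) and the BMP antagonist GREM1 (5.40 ± 0.43) were highest. HGF was neither, at -1.55 ± 1.01 (below without dog 3, at -2.16), and IGF1 had 33 reads in dog 4 alone. Among 29 genes of extracellular vesicle biogenesis 23 were above, 2 below and 4 neither, with ANXA2 (6.92 ± 0.29), HSPA8 (5.92 ± 0.35) and the tetraspanin CD63 (5.79 ± 0.20) leading and SMPD3 and RAB27B below. Of 35 matrix proteases and inhibitors 25 were above, 6 below and 2 neither. LOXL2 (8.08 ± 0.31), the collagen chaperone SERPINH1 (7.93 ± 0.12) and the gelatinase MMP2 (7.40 ± 0.83) were among those above.

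Markers of lineage and of other cell types showed cell cycle, stromal and contractile genes above the median and blood lineage genes near the floor. Of 35 cell cycle genes 21 were above the median detected gene and none below (1 below without dog 3 or 4), with MCM6 (3.85 ± 0.36), MCM4 (3.32 ± 0.63) and TOP2A (3.29 ± 0.35) highest. Of 20 adipose stromal progenitor genes 12 were above, with the proteoglycan gene DCN and the tissue factor gene F3 (5.71 ± 1.47) highest, and 5 were below, DLK1 (-3.66 ± 0.36) lowest. In the smooth muscle and pericyte list 12 of 17 were above and 2 below (1 without dog 3 or 4). TAGLN (7.38 ± 0.68), ACTA2 (7.34 ± 1.04) and CALD1 (6.08 ± 0.52) led it, whereas RGS5 had 0 reads and DES 3 and 4 reads in dogs 3 and 4. The expected MSC markers and this list differed by 0.53 ± 0.83, higher in 3 of 4 dogs (exact sign-flip p = 0.25, adjusted 0.27 by Benjamini-Hochberg). The difference was 0.16 without dog 3 and 0.83 without dog 4. Of 15 adipocyte genes RBP4 (5.76 ± 0.53), FASN (5.40 ± 0.35), SCD (3.52 ± 0.75) and PNPLA2 (1.60 ± 0.43) were above and 7 were below, and PNPLA2 lost its call without dog 1 (1.22), 2 (1.44) or 4 (1.24). Among 17 endothelial genes FLT1 (3.07 ± 0.36) was above and 6 were below, and of 16 myeloid genes none was above, 5 were below and 10 were not detected, with 3, 2, 3 and 4 below without dogs 1 to 4 in turn.

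The spread between the 4 dogs exceeded the middle 95% of random lists in 17 of 32 lists, and without dog 4 in 8 of these 17. The median SD between dogs over detected members was 0.93 for antimicrobial chemokines, against 0.46 in random lists matched on level, and 0.76 against 0.36 for immunomodulatory genes. It was 0.70 against 0.29 for smooth muscle and pericyte genes, 0.66 against 0.35 for growth factors, 0.57 against 0.26 for the matrix list, 0.77 against 0.27 for mitochondrially encoded genes and 0.60 against 0.29 for senescence genes. Each of these 7 lists lay at percentile 99.98 or higher of the matched random lists in both of 2 draws, as did the expected MSC markers and cell cycle genes. The MSC markers fell under the limit of 97.5 without dog 1 (97.0) or dog 4 (97.2) and the cell cycle genes without dog 4 (89.7), while the 7 lists stayed above it without any 1 dog. Without dog 4 the median SD was 0.48 for immunomodulatory genes, 0.39 for senescence genes and 0.42 for antimicrobial peptides and proteins, and without dog 2 it was 0.49 for mitochondrially encoded genes. Antimicrobial peptides and proteins (0.65 against 0.44, percentile 99.6) were among the 17, but not without dog 4 or dog 2, when the percentile was 77.3 or 95.8. Vesicle genes did not exceed it (0.26 against 0.26, percentile 46.4). The largest spreads among genes above the median level belonged to the receptor SORCS1 (SD 2.82), the collagen COL6A3 (2.58) and the myosin kinase MYLK (2.45). MYLK had 5839, 2880, 662 and 17670 reads in dogs 1 to 4, and COL6A3 had 3666, 1647, 19409 and 100. No gene passed the test of variability against the trend (limma, Benjamini-Hochberg, 0 of 17200, smallest adjusted p = 0.0796). Of the tested genes, 895 had an unadjusted p under 0.05 in this F test, where the fitted prior gives 860. That prior was fitted to these same variances, so a count near 860 is largely built in. The count does not measure how far the dogs differ. Without dog 4, 1 gene passed. With a robust prior 23 genes passed, 18 of them named, among them IL11, PTGS2, CXCL8, POSTN, ELN and FBN2.

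Dog 4 was the library least like the others. Its correlation with the other dogs across detected genes was 0.945 to 0.955 (Pearson), while dogs 1 to 3 correlated at 0.972 to 0.978, and genes are not independent replicates. All pairs differed far beyond counting noise, with a chi-square per degree of freedom of 40.1 to 106, so no library was a copy of another. Among 8555 detected genes above the median level, dog 4 stood apart from the other 3 in 295 (3.45%), dog 1 in 86, dog 2 in 38 and dog 3 in 79, where chance gives 1.25% per library. Over members above the median detected gene, dog 4 was higher than the mean of the other 3 dogs by a median of 1.47 log2 units in 4 chemokines, by 1.08 in 13 smooth muscle genes, all 13 of them higher, by 0.91 in 12 immunomodulatory genes, 8 of them higher, and by 0.54 in 28 growth factors, 22 of them higher. It was lower by a median deviation of -0.72 in 32 cell cycle genes, 1 of them higher, and of -0.72 in 35 ribosomal protein genes, none of them higher. Dog 3 deviated the other way by as much or nearly as much in some of these lists: -1.48 in the chemokines, -1.06 in smooth muscle genes, -0.82 in immunomodulatory genes and 0.56 in cell cycle genes. Each dog is part of the mean that the others are set against. A high dog 4 therefore lowers the value of dog 3, and the reverse, so part of these opposite values is built in. The 12 mitochondrially encoded genes set dog 2 (-0.84) apart from dogs 1 (0.55) and 4 (0.56), with 7 of them higher in dog 4. By share of reads, however, dogs 2 and 4 were the lowest: the whole mitochondrial list held 2.75%, 2.16%, 3.15% and 2.20% in dogs 1 to 4. IL6 had 57, 4, 14 and 300 reads in dogs 1 to 4, IL11 had 183, 31, 23 and 722 and PTGS2 had 774, 256, 257 and 2009, with dog 4 the shallowest library. Dog 4 also had the largest share of reads in unnamed genes, 11.1% against 6.84% to 8.54%, and a single unnamed gene took 6.54% of its reads. The directions of these list values were the same after thinning all libraries to the depth of dog 4.

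**Figure D3:**
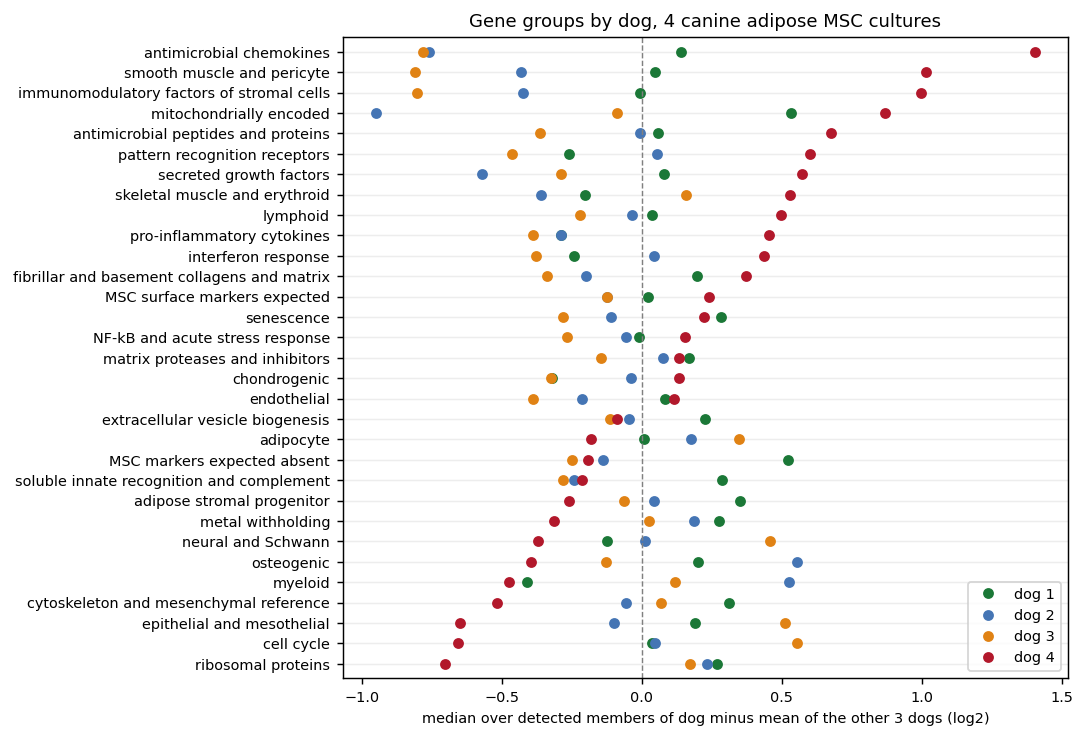
Deviation of each dog from the mean of the other 3 dogs (x axis, log2, median over detected list members, centred on the median of all detected genes) for each gene list with at least 5 detected members (y axis). Points are dogs; dog 4 lies at 1.40 for antimicrobial chemokines and at -0.70 for ribosomal proteins, dog 3 at -0.81 for smooth muscle and pericyte genes and dog 2 at -0.95 for mitochondrially encoded genes, and lists with many genes near the floor also carry its lower depth.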

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

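All the tests of explanations below were chosen after the results they address were seen. Of 230 detected genes that the naming rule took or the text names, 41 had a dog far from the other 3, where chance gives about 1 in 20, and 20 of them were named for standing apart. Chance counts do not apply to genes named after their values were seen. Among the 171 genes that the rule took by level alone, 18 had a dog far apart against 8.55 by chance, and in 13 of the 18 it was dog 4. Values are the distant dog minus the mean of the others, on the log2 scale.

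Dog 4 lay far above in KRT18 (5.08), CSF3 (4.66), WNT5A (4.00), DLA88 (2.65), HAPLN1 (2.62), IL23A (1.23), SOX5 (1.15) and CD68 (0.92). It lay far below in SORCS1 (-5.63), GAP43 (-3.41), FRMD3 (-3.22), EPHB2 (-2.96), ALAS2 (-1.82), VIM (-1.05), RPL3 (-0.96), RPS4X (-0.92), RPL13A (-0.80), COL1A1 (-0.80), COL1A2 (-0.56) and KLF4 (-0.55). Dog 1 lay apart in BMP2K (2.99), ITIH5 (2.06), GALNT1 (1.42), CD63 (0.39), TLR4 (-0.54), CKM (-0.67), SLC9A5 (-1.24) and TMTC1 (-1.44). Dog 2 lay apart in CYP1B1 (1.43), TFPI (0.55), CAVIN1 (-0.59), PODN (-1.01) and LIPG (-2.32). Dog 3 lay apart in DOCK11 (0.84), SLC41A3 (0.76), CCNE2 (0.51), TNFSF10 (-0.63), TMEM64 (-0.94), SLC17A9 (-0.97), CA12 (-1.02) and PI3 (-1.66). CKM, ALAS2, PI3, CD68, TLR4 and IL23A have at most 33 reads in any dog.

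List medians stood apart with dog 4 for antimicrobial chemokines (1.44), immunomodulatory factors (2.55), secreted growth factors (1.09), epithelial and mesothelial genes (-0.76) and ribosomal proteins (-0.56), and with dog 1 for pattern recognition receptors (-0.48). The chemokine medians of dogs 1 to 3 and the epithelial median of dog 4 lie at the value of 0 reads, which by itself can set these apart. A shift of a list median is not the shift of a typical member. Taken gene by gene over detected members, the median deviation of dog 4 was 1.00 for immunomodulatory factors, 0.57 for growth factors and -0.70 for ribosomal proteins. The differences of the antimicrobial peptide list from the chemokines (-1.42), the immunomodulatory factors (-2.53) and the growth factors (-1.07) stood apart with dog 4 too, but the peptide median lies at the value of 0 reads in every dog, so these only restate the medians of the other lists.

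Dog 4 combined high contractile and chemokine genes with low ribosomal and cell cycle genes, while dog 3 deviated the other way in smooth muscle (-0.81) and cell cycle genes (0.55). Part of this opposition is built in, since dog 4 is in the mean that dog 3 is set against. The lower depth of dog 4 was tested by thinning every library to its size: dog 4 still stood apart in 267 genes above the median, against at most 90 in another dog, which argues against depth as the whole cause. Admixed smooth muscle cells or pericytes may contribute: the median deviation of MYH11, DES and RGS5 was 0.29 against 4.30 for MYLK. RGS5 has 0 reads in all dogs and DES at most 4, so the 0.29 is the value of MYH11. It rests on that gene alone, and this stays open. Differences between the dogs themselves were not tested, since each dog has 1 culture and the dog, its culture and its library cannot be separated.

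CD79A was the only expected-absent marker above the median, in all 4 dogs. B cells were tested by the reads of CD79B, MS4A1, PTPRC and BLK, which together made 0.0193% of the reads of CD79A (5 against 25939), far below what B cells would bring. Reads of the neighbouring RPS19 counted as CD79A remain a candidate explanation. CD79A minus the ribosomal protein median varied between dogs with an SD of 0.23, at percentile 20.2 of 604 genes of the same level. CD79A alone had an SD of 0.16, so subtracting that median did not make it steadier. The ribosomal median itself had an SD of 0.28, under the 0.38 median of these genes. A gene steady between dogs therefore scores low here too, and the percentile cannot decide. Transcription of CD79A in the stromal cells themselves was not tested.

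S100A8 was the highest of the antimicrobial peptide genes. Granulocytes or macrophages in the cultures were tested by 8 measured myeloid genes (MPO, ELANE, S100A12, LYZ, CYBB, FCER1G, SPI1 and AIF1), whose reads made 0.246% of those of S100A8 (46 against 18707), so such cells would lack their other abundant transcripts. Reads of neighbouring S100 genes counted as S100A8 may still contribute: S100A8 minus the median of the cytoskeleton and mesenchymal reference list had an SD of 0.28, at percentile 34.4 of 617 genes of the same level, which leaves this open. Transcription of S100A8 in the stromal cells themselves also stays open and was not tested.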

How the results depend on the processing

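The setting that leaves out CD79A and the thinning of reads were chosen after seeing the data. Counts of genes above and below the median detected gene moved with the reference and the genes tested, by construction: 3729 above with the reference over genes with reads in all 4 dogs, 11406 above and 0 below with the reference over all genes, 2830 below when only genes with reads in all dogs were tested and 19520 when all genes were. Without each dog in turn, 4887 to 5230 were above and 5304 to 5749 below. Variable genes numbered 23 with a robust prior and 0 to 1 without a dog, and 0 under the 6 other settings. The robust prior used its largest degrees of freedom for every gene, which eases calls. How far this accounts for the 23 was not tested, nor was the cause of the call without a dog. Of the antimicrobial peptide list, 5 were above and 0 below with the reference over all genes, 2 below when only genes with reads in all dogs were tested and 25 when all were. Of the expected MSC markers, 4 were below with the reference over genes in all dogs and at distance 0, 0 with the reference over all genes, 1 when only genes in all dogs were tested, and 2 to 4 without a dog. Of the markers expected absent, 4 were above and 0 below with the reference over all genes, 14 below when all genes were tested and 0 above without CD79A.

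With the reference over all genes, IL23A (1.66), SOX9 (1.65), CD80 (1.69) and CIITA (1.64) turned from below to above. The antimicrobial peptide list minus chemokines ranged from -0.47 to 0 without a dog, the expected MSC markers minus the smooth muscle list from 0.16 to 0.83, and 83 of the 84 alternative list differences kept their direction. With the median over all members many of them could not reverse. The peptide, expected-absent, myeloid and lymphoid medians lie at the value of 0 reads. The percentile of list spread ranged without a dog from 77.3 to 99.9 for antimicrobial peptides, 85.0 to 99.99 for soluble innate genes, 91.2 to 100 for metal withholding, 17.3 to 99.9 for interferon response, 79.5 to 99.4 for NF-kB and stress, 97.0 to 99.99 for expected MSC markers, 89.7 to 100 for cell cycle, 91.7 to 99.9 for adipocyte and 12.03 to 99.96 for ribosomal genes, with the lowest value without dog 4 except for the MSC markers, where it was without dog 1. It fell to 89.7 for NF-kB and stress under quantile normalization and to 83.3 for ribosomal proteins with the mean. Other lists passed 97.5 only under an alternative: with the mean, pattern recognition (97.9), matrix proteases (98.4), epithelial and mesothelial (99.99) and skeletal muscle and erythroid genes (98.9); with quantile normalization, the cytoskeleton reference (99.5); without dog 1, osteogenic genes (97.6); without dog 3, matrix proteases (98.9), skeletal muscle and erythroid genes (99.5) and the cytoskeleton reference (98.2); and without dog 4, matrix proteases (99.4). The cause was not tested. Of 2937 alternative levels of named genes, 2712 kept their side of the threshold, and the called ones among them also kept their direction. Levels not called in either setting may have changed direction. Of 231 alternative percentiles of list level, 54 moved by more than their SD between dogs. Most of these came with only detected members, where 19 of 33 lists moved, or with the mean, where 18 did.

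No paired analysis was possible because there is 1 group. Alternatives that need exon lengths were not run. The spread already uses only detected members. The depth of dog 4, 7474011 reads, limits low genes most.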

Other observations

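The test of DGUOK below was chosen after its values were seen. Lineage genes not yet described were mostly low. Of 12 osteogenic genes RUNX2 (1.71 ± 0.69) was above the median detected gene, though not without dog 1 (1.31), 2 (1.28) or 3 (1.53), 3 were below, 5 neither and 3 not detected, and of 12 chondrogenic genes 8 were below and none above, SOX9 at -1.75 ± 0.74 (not called without dog 3, at -1.60). Of 17 lymphoid genes 4 were below (2 without dog 1) and 11 not detected, CD79A being above. In the neural and Schwann list the myelin gene PMP22 and NCAM1 (1.81 ± 0.50) were above and 3 below. None of 11 epithelial and mesothelial genes was above and 5 were below (3 without dog 1), and of 12 skeletal muscle and erythroid genes 4 were below (2 without dog 4) and 7 not detected. Of 5 pluripotency genes KLF4 (2.63 ± 0.27) was above and SALL4 below, the latter with reads in too few libraries to be tested without dog 2 or 3. Of 20 senescence genes 13 were above and 3 below, and the cell cycle inhibitor CDKN1A stood at 3.54 ± 0.83. Ribosomal proteins (35 of 36 above, RPS23 below), mitochondrial genes (12 of 13 above, 1 below without dog 4), the cytoskeleton and mesenchymal reference list (16 of 16) and 4 X-linked genes (4 of 4) were high.

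Single genes varied against their relatives. COL6A3 had an SD of 2.58 between dogs, while COL6A1, which encodes a chain of the same collagen, had 118989, 76434, 79078 and 31210 reads and an SD of 0.15. DGUOK, a mitochondrial nucleoside kinase gene, had 2931, 587, 443 and 3916 reads and lies beside the smooth muscle actin gene ACTG2, which was not analysed here under its own symbol. Reads of ACTG2 counted as DGUOK were tested as a candidate explanation. The SD of DGUOK between dogs was 1.97 alone and 0.98 after the median of the smooth muscle and pericyte list was subtracted, at percentile 39.0 of 631 genes of the same level. That list median was 3.12, 2.71, 2.04 and 4.57 in dogs 1 to 4, and DGUOK ranked the dogs in the same order. Subtraction removes the list at its own size only, so the percentile cannot judge a gene that moves with the list by larger steps. The explanation stays open. MT-ATP8 had 14, 17, 73 and 249 reads. KRT18 had 9, 9, 25 and 435 reads, with 0 reads of CDH1 in every dog. BMP2K had 26904, 2952, 2037 and 1219 reads. The class I gene DLA88 had 907, 743, 859 and 2117 reads, highest in the shallowest library. CSF3 had 4, 0, 3 and 161 reads.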
